A study of Mus musculus with 6 samples.

How the data were processed

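Gene expression was measured by RNA sequencing in 6 libraries, each made from a pool of dye-labelled mouse spinal cord motor neurons picked into a tube. Per the labels' protocols, whole transcripts were amplified with a SMART-Seq HT kit over 20 PCR cycles, with no molecular identifiers named. Synthetic spike-in RNA is named in the labels as a quality control, and no spike-in rows were among the genes of the table. The labels also speak of 3 batches of libraries without saying which library belongs to which batch.

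The deposited values are read counts per Ensembl gene, whole numbers that were not normalised. Per the submitters' processing notes, FastQC, HISAT2 and HTSeq were used with the mouse build mm10. Versions, the gene annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. The deposited table of all libraries held the same counts as the deposited files of single libraries. Of 53858 genes, 25345 had 0 counts in every library. Identifiers were matched to GENCODE M21 on GRCm38, the assembly also called mm10, which held 53772 of them (99.8%), and coordinates are given 1-based from it. Reads of some overlapping genes appear to be counted for both. An antisense gene inside *Malat1* had 97.6 to 99.0% of the counts of *Malat1* in each library. Of 2510 pairs of overlapping tested genes, 4 had counts within a factor of 1.1 of each other in all libraries, all 4 on opposite strands. Overlapping, antisense and near-identical genes are therefore uncertain.

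Libraries were grouped by the dye combination in the labels, 3 with DiO only and 3 with DiO and DiI, and no library was left out. Total counts ran from 2997714 to 6563403, and 3 counts corresponded to 0.457 to 1.00 CPM in a library. The counts were analysed in R 4.3.3. Genes with low counts were removed with edgeR's filterByExpr by group, which kept 12954 genes with 99.2% of all counts. Libraries were scaled with TMM factors, and CPM values are TMM-scaled unless given as summed CPM or shares, which use total counts. Groups were compared with the robust quasi-likelihood F-test of edgeR 4.0.16, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common biological coefficient of variation was 0.587. Standard errors of log2 fold changes were obtained from the fold change and its F statistic.

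Gene lists were fixed before the data were examined. Of 35 lists, 28 had at least 5 tested members and were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 28 lists. Alternatives were an estimated correlation and fry, whose p tests whether the genes of a list move on balance in a common direction. Single values were compared with exact two-sided permutation tests, which cannot go below p = 0.1 with 3 against 3. Named genes were the up to 12 genes per direction that passed with groups that did not overlap and a mean of at least 5 CPM, filled up with the genes of smallest unadjusted p under the same limits, which then failed the threshold. To these were added up to 4 members of smallest p per described list, and a fixed set that includes *Chat*, *Isl1*, *Prph*, *Atf3*, *Gap43*, *Sprr1a*, *Jun*, *Sox11*, *Gal*, *Mbp*, *Aqp4*, *C1qa*, *Slc17a6* and *Gad1* whatever their test. *Aldh1l1*, *S100b*, *Vip*, *Npy*, *Uts2*, *Calcb*, *Ptgds*, *Clu*, *Cst3*, *Ndrg1*, *Penk* and *Sst* were named after their values were seen. Predicted genes without a common symbol were counted and not named, and not every gene chosen by these rules is printed.

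The alternatives tried were other scalings, no filter and a stricter filter of 10 counts in 5 libraries, DESeq2 1.42.0, limma voom with sample quality weights, a replicate block, other thresholds, and leaving out each library in turn. Thinning to the smallest library and camera on ranks were added after seeing the data. The tests were tested on simulated data, drawn from the means and library sizes of the real samples with 200 genes changed by known folds. With no changed genes edgeR made 1 call, and 4.57% of genes had an unadjusted p under 0.05. A simulated list of 30 moved genes was recovered by camera (adjusted p = 2.0e-11, and adjusted p = 0.0355 with an estimated correlation), with 0 of 27 other lists called. Simulated genes were drawn independently of each other. The simulation therefore does not measure how often lists of correlated genes are called falsely, and the regeneration-associated list had an estimated correlation of 0.229. Figures were drawn with matplotlib 3.10.9.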

Results

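Poly(A) RNA was sequenced from small pools of injured spinal cord motor neurons of wild-type mice, collected on day 6 after a crush of the sciatic nerve. Lipophilic carbocyanine dyes marked the cells from their axons. DiO was given proximal to the injury on day 0 and filled the injured motor neurons. DiI was given at a distal site on day 2 and marked the neurons whose regrowing axons were first to arrive there. The design has 2 groups of 3 pools each, named here DiO-only pools (DiO without DiI) and double-labelled pools (DiO with DiI). Each pool held 10 to 15 picked fluorescent cells per the labels, whose lysis step allows up to 20. The total counts of DiO-only pools 1, 2 and 3 were 6505086, 3747145 and 5196844, and those of double-labelled pools 1, 2 and 3 were 4981232, 2997714 and 6563403. The labels do not say that the pools came from separate animals, so p-values measure only the spread between these samples, which may be technical.

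Both groups of libraries carried motor neuron transcripts. *Chat*, the acetylcholine-synthesising enzyme, stood at 78.4 ± 21.5 CPM (counts scaled to a common library size with TMM factors; SD, n = 3) in DiO-only pools and at 111 ± 27.3 in double-labelled pools. The motor neuron transcription factor gene *Isl1* stood at 31.9 ± 3.55 and 25.3 ± 8.93 CPM, and the intermediate filament gene *Prph* at 2296 ± 680 and 1671 ± 688 CPM. These 3 genes had overlapping groups, with log2 fold changes of 0.50 ± 0.34 (SE), -0.33 ± 0.42 and -0.46 ± 0.39 for the double-labelled against the DiO-only pools (edgeR adjusted p = 0.950, 0.978 and 0.966). *Chat* overlaps *Slc18a3* and a predicted gene, and these cannot be told apart by reads in the shared part. *Gad1*, of inhibitory neurons, had 40 counts over all 6 libraries and *C1qa*, of microglia, had 97, too few for the test. *Slc17a6*, of excitatory interneurons, stood at 26.2 ± 31.5 and 6.84 ± 5.13 CPM (edgeR adjusted p = 0.872). Mitochondrially encoded genes took 6.61 ± 3.68% and 9.39 ± 7.54% of counts (SD, n = 3; exact two-sided permutation p = 0.6). More genes had at least 1 count in DiO-only pools, 20249 ± 2640, than in double-labelled pools, 16039 ± 407, with no overlap between the groups (exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). After thinning every library to 2997714 counts the numbers were 19236 ± 2137 and 15702 ± 668, again without overlap.

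Genome-wide, the double-labelled pools resembled each other less than the DiO-only pools did. Across the 12954 tested genes, the mean Pearson correlation of log2 CPM was 0.888 among DiO-only pools, 0.770 among double-labelled pools and 0.815 between the groups, where genes are not independent replicates. The first principal component held 33.8% of the variance and set double-labelled pool 1 apart from the other 5 libraries.

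The comparison of double-labelled with DiO-only pools asks which transcripts differ between motor neurons whose axons had regrown to the distal site early and injured motor neurons without the distal dye. In the double-labelled pools, injury-response and growth genes such as *Gal*, *Atf3*, *Gap43* and *Tubb6* had lower counts, with 34 of 35 regeneration-associated genes below their DiO-only level. Transmitter receptor genes such as *Gria3* and *Chrm2* and markers of oligodendrocytes and astrocytes such as *Mbp* and *Slc1a2* had higher counts. These differences were called for gene lists under a preset correlation between genes. No single gene passed in the main edgeR test, and no list passed with an estimated correlation. DESeq2 without the filter on low counts called 75 genes, *Gal*, *Tubb6*, *Mbp* and *Slc1a2* among them. With edgeR, 79 genes were called without that filter and 23 with the replicate numbers as a block.

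Of 12954 genes tested with edgeR's quasi-likelihood test, 0 had an adjusted p under 0.05, and the smallest adjusted p was 0.308. At an unadjusted p under 0.05 there were 753 genes (5.81%), 412 higher and 341 lower in double-labelled pools. The groups did not overlap for 1675 genes (12.9%), where chance gives 10%. DESeq2, started from all 53858 genes without the filter on low counts, called 75 genes, 39 higher and 36 lower. The filtered limma voom fit with sample quality weights called 0. Without a filter on low counts edgeR called 79, and with the replicate numbers as a block, which the labels do not say to be pairs, it called 23 (12 higher, 11 lower). On simulated counts for this comparison, over 12954 genes, edgeR recovered 0% of the genes changed 2-fold, 32.8% of those changed 4-fold and 62.1% of those changed 8-fold, with 2 false calls among 65. DESeq2 recovered 3.0%, 52.2% and 71.2%, with 28 false calls among 112. This simulated DESeq2 run held only the 12954 filtered genes, so its rates do not measure the 75 calls from unfiltered counts.

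The regeneration-associated list, genes that peripheral neurons are known to induce after axon injury, fell as a group in double-labelled pools. Of its 35 tested members 34 were lower, 21 of them at an unadjusted p under 0.05, with a median log2 fold change of -0.93 (camera adjusted p = 5.4e-12 in limma). With an estimated correlation the call was lost (adjusted p = 0.258). Over all genes tested 0 members passed in edgeR, and adjusted over the list alone 6 did, namely *Anxa2*, *Smad1*, *Gap43*, *Gal*, *Vip* and *Tuba1a*. DESeq2 called *Gal* (adjusted p = 0.00307), *Anxa2* (0.0360) and *Vip* (0.0397) over all genes. *Gal* encodes the neuropeptide galanin (ENSMUSG00000024907; mm10 chromosome 19, 3409915 to 3414544, minus strand). Its level was 4757 ± 4621 CPM in DiO-only pools and 47.1 ± 68.4 CPM in double-labelled pools (SD, n = 3). The lowest DiO-only library stood at 1363 CPM and the highest double-labelled library at 126 CPM. *Atf3*, a stress-induced transcription factor gene (ENSMUSG00000026628; chromosome 1, 191170296 to 191218039, minus strand), stood at 1064 ± 272 and 477 ± 232 CPM. *Gap43*, of a growth cone protein (ENSMUSG00000047261; chromosome 16, 42248442 to 42340651, minus strand), stood at 2322 ± 658 and 1053 ± 123.4 CPM. The transcription factor genes *Jun* and *Sox11* stood at 296 ± 67.2 against 146 ± 54.5 CPM and at 92.0 ± 27.0 against 43.2 ± 15.5 CPM. *Jun* shares its locus with the antisense gene *Junos*. None of these 5 genes had overlapping groups, and their edgeR adjusted p over all genes ran from 0.616 to 0.720. *Sprr1a*, at 5723 ± 4202 and 1828 ± 1698 CPM, had overlapping groups and an edgeR adjusted p of 0.775. *Anxa2*, of a membrane-binding annexin, stood at 2001 ± 341 and 840 ± 113 CPM, and *Smad1*, a mediator of bone morphogenetic protein signals, at 67.2 ± 13.8 and 24.9 ± 2.22 CPM. Libraries in which this list was lower also had fewer detected genes, 16039 ± 407 against 20249 ± 2640, and higher oligodendrocyte markers. The summed CPM of interneuron markers without *Npy* was lower too, 22.6 ± 10.8 against 103 ± 30.04 with no overlap. That list was not tested, and its member *Slc17a6* stood at 62.6 CPM in DiO-only pool 1 but at 8.02 and 7.90 CPM in pools 2 and 3. Its member *Sst*, a neuropeptide gene, stood at 36.9 ± 59.2 CPM in DiO-only pools (SD, n = 3), so uneven single genes made up part of the sum.

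**Figure D1:**
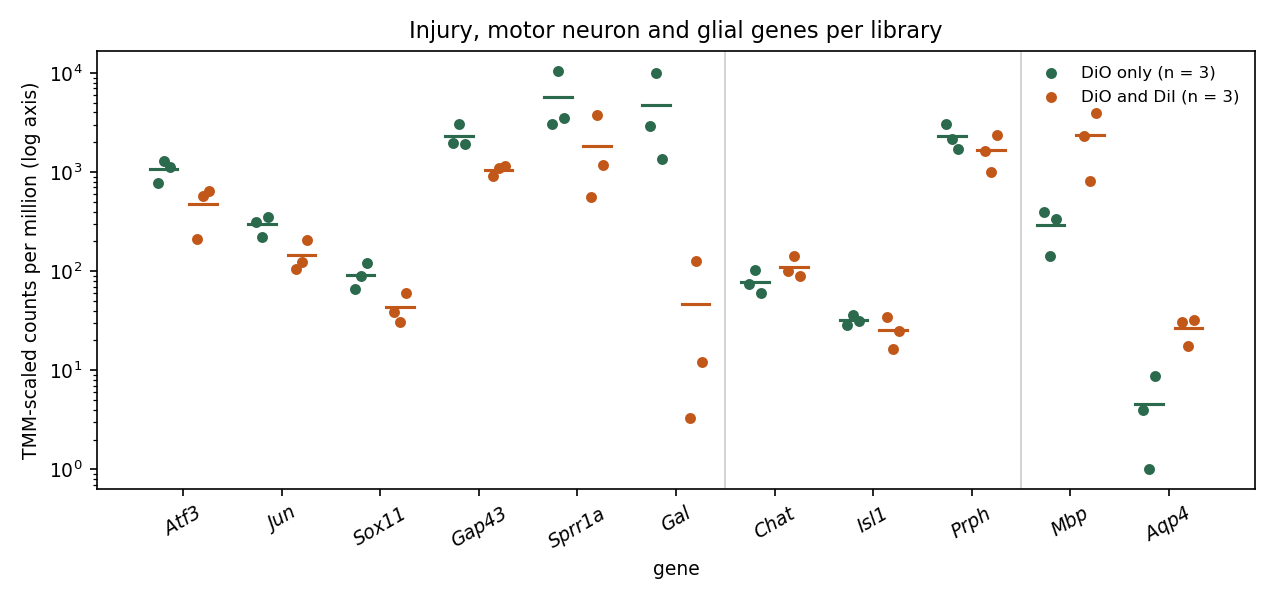
TMM-scaled CPM on a log axis for 6 injury-response genes (left), 3 motor neuron genes (middle) and 2 glial genes (right), with each point a library and each bar the mean of 3 libraries. *Gal* lies above 1000 CPM in the DiO-only pools and at or below 126 CPM in the double-labelled pools, whereas *Chat*, *Isl1* and *Prph* overlap between the groups.

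The list of growth cytoskeleton genes also fell as a group. Of 41 tested members 31 were lower, 13 at an unadjusted p under 0.05, with a median log2 fold change of -0.67 (camera adjusted p = 0.000281 in limma, and adjusted p = 0.258 with an estimated correlation). The members of smallest p encode tubulins and *Gap43*. *Tubb6* stood at 663 ± 206 CPM in DiO-only pools and 207 ± 31.7 in double-labelled pools (SD, n = 3; log2 fold change -1.68 ± 0.33, SE; edgeR adjusted p = 0.357) and was the only member to pass adjusted over the list alone, with 0 passing over all genes. *Tubb2a* stood at 1858 ± 452 and 791 ± 280 CPM, and *Tuba1a*, which is on the regeneration list too, at 3862 ± 487 and 1864 ± 308 CPM. Both lists share 5 members. Tubulin genes are near-identical copies, so the authors' counting could split or drop reads between them. The libraries with lower growth cytoskeleton genes also had fewer detected genes and higher glial markers.

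Transmitter receptor genes rose as a group in double-labelled pools. Of 22 tested members 19 were higher, 11 at an unadjusted p under 0.05, with a median log2 fold change of 0.81 (camera adjusted p = 7.0e-08 in limma, and adjusted p = 0.224 with an estimated correlation). Adjusted over the list alone 6 passed in edgeR and over all genes 0. The glutamate receptor genes *Gria3* and *Grin2a* stood at 46.1 ± 17.7 against 131 ± 39.8 CPM and at 20.6 ± 4.42 against 57.1 ± 16.1 CPM (SD, n = 3). The muscarinic receptor gene *Chrm2* stood at 30.3 ± 14.8 and 106 ± 59.5 CPM. Each of these 3 genes had groups that did not overlap. Glial marker lists were higher in the same libraries, with medians of 2.01 for oligodendrocytes and 2.45 for astrocytes, and fewer genes were detected.

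Voltage-gated channel genes rose as a group, with 27 of 36 members higher, 3 at an unadjusted p under 0.05, and a median log2 fold change of 0.33 (camera adjusted p = 0.0113 in limma, and adjusted p = 0.407 with an estimated correlation). The potassium channel gene *Kcna2* stood at 155 ± 41.9 and 394 ± 199 CPM, and the sodium channel gene *Scn1a* at 169 ± 52.2 and 363 ± 83.3 CPM (SD, n = 3). Over all genes and adjusted over the list alone, 0 members passed in edgeR. The call was lost without double-labelled pool 2 (camera adjusted p = 0.188) or pool 3 (0.0700). The mean log2 CPM of the list relative to the DiO-only mean was 0.01 in double-labelled pool 1, inside the DiO-only range of -0.23 to 0.12. Glial markers were higher and fewer genes detected in the double-labelled libraries here too.

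Markers of alpha and fast motor neurons passed upward with members on both sides. Of 9 tested members 7 were higher, with a median log2 fold change of 0.94 (camera adjusted p = 0.0188 in limma, and adjusted p = 0.323 with an estimated correlation). Adjusted over the list alone, *Chodl* and *Mmp9* passed upward and *Calca* downward in edgeR, and over all genes 0 passed. *Chodl*, a marker of fast motor neurons, stood at 192 ± 37.7 and 647 ± 434 CPM, and *Mmp9*, a metalloproteinase gene of fast motor neurons, at 13.7 ± 13.8 and 69.2 ± 24.6 CPM (SD, n = 3). *Calca*, of the calcitonin gene-related peptide, stood at 8938 ± 5419 and 3023 ± 867 CPM, so that the summed CPM of the list was lower in double-labelled pools, 8226 ± 1929 against 13202 ± 4131, while its median and test pointed up. The call was lost without DiO-only pool 3 (camera adjusted p = 0.134) or double-labelled pool 2 (0.126). The wider motor neuron identity list did not pass, with 13 of 21 members higher and a median of 0.26 (camera adjusted p = 0.0951). Markers of gamma and slow motor neurons did not pass either, with 5 of 9 higher (camera adjusted p = 0.762). As for the other lists, the double-labelled libraries differed in glial markers and detected genes as well.

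Proteasome genes and immediate early genes passed downward with small medians. Of 35 proteasome genes 31 were lower, 3 at an unadjusted p under 0.05, with a median log2 fold change of -0.33 (camera adjusted p = 0.00887 in limma, and adjusted p = 0.567 with an estimated correlation). *Psmd11*, for example, stood at 122 ± 14.2 and 75.7 ± 11.1 CPM (SD, n = 3). Of 10 immediate early genes 9 were lower, with a median of -0.39 (camera adjusted p = 0.0499 in limma, and adjusted p = 0.307 with an estimated correlation). *Zfp36*, of an mRNA decay factor, stood at 6.22 ± 4.24 and 0.714 ± 0.653 CPM. In both lists 0 members passed in edgeR, over all genes or adjusted over the list alone. The proteasome call was lost without double-labelled pool 2 (camera adjusted p = 0.272), double-labelled pool 3 (0.180) or DiO-only pool 1 (0.0908), and the immediate early call without double-labelled pool 2 (0.0977), double-labelled pool 3 (0.0609) or DiO-only pool 3 (0.0557). The mean log2 CPM of the proteasome list relative to the DiO-only mean was 0.03 in double-labelled pool 1, inside the DiO-only range of -0.15 to 0.18. The double-labelled libraries, that one included, had higher glial markers and fewer detected genes.

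Oligodendrocyte and astrocyte markers rose as groups in double-labelled pools. All 12 tested oligodendrocyte markers were higher, 9 at an unadjusted p under 0.05, with a median log2 fold change of 2.01 (camera adjusted p = 2.7e-08 in limma, and adjusted p = 0.0892 with an estimated correlation). Of 11 astrocyte markers 9 were higher, 7 at an unadjusted p under 0.05, with a median of 2.45 (camera adjusted p = 3.3e-07 in limma, and adjusted p = 0.224 with an estimated correlation). Adjusted over the list alone, 7 oligodendrocyte and 6 astrocyte markers passed in edgeR, and over all genes 0. The summed CPM of the oligodendrocyte list was 510 ± 237 and 3332 ± 2142 (SD, n = 3). That of the astrocyte list was 1040 ± 56.5 and 1652 ± 663, less apart than the median, with double-labelled pool 2 at 1000 inside the DiO-only range of 986 to 1099. *Mbp*, of myelin basic protein (ENSMUSG00000041607; chromosome 18, 82475146 to 82585637, plus strand), stood at 292 ± 132 CPM in DiO-only pools and 2352 ± 1551 CPM in double-labelled pools (SD, n = 3; log2 fold change 3.01 ± 0.58, SE; edgeR adjusted p = 0.357). The astrocytic glutamate transporter gene *Slc1a2* stood at 13.3 ± 2.34 and 72.6 ± 28.7 CPM, the sodium pump subunit gene *Atp1b2* at 5.04 ± 1.04 and 56.9 ± 40.5 CPM, and the water channel gene *Aqp4* at 4.57 ± 3.92 and 27.0 ± 8.21 CPM. The astrocyte markers *Aldh1l1* and *S100b* had log2 fold changes of -1.27 and -0.13, which turned upward without DiO-only pool 3 for *Aldh1l1* (0.46), and for *S100b* without DiO-only pool 2 (0.79), with limma voom (0.49), with the replicate block (0.12) and with total-count scaling (0.01). The libraries with higher glial markers were those with fewer detected genes. Microglia markers did not pass, with 5 of 7 lower and a median of -0.46 (camera adjusted p = 0.244), nor did endothelial and pericyte markers, with 3 of 5 lower and a median of -0.36 (camera adjusted p = 0.0956), although the latter passed downward in 4 of the 6 runs that left out 1 library.

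**Figure D2:**
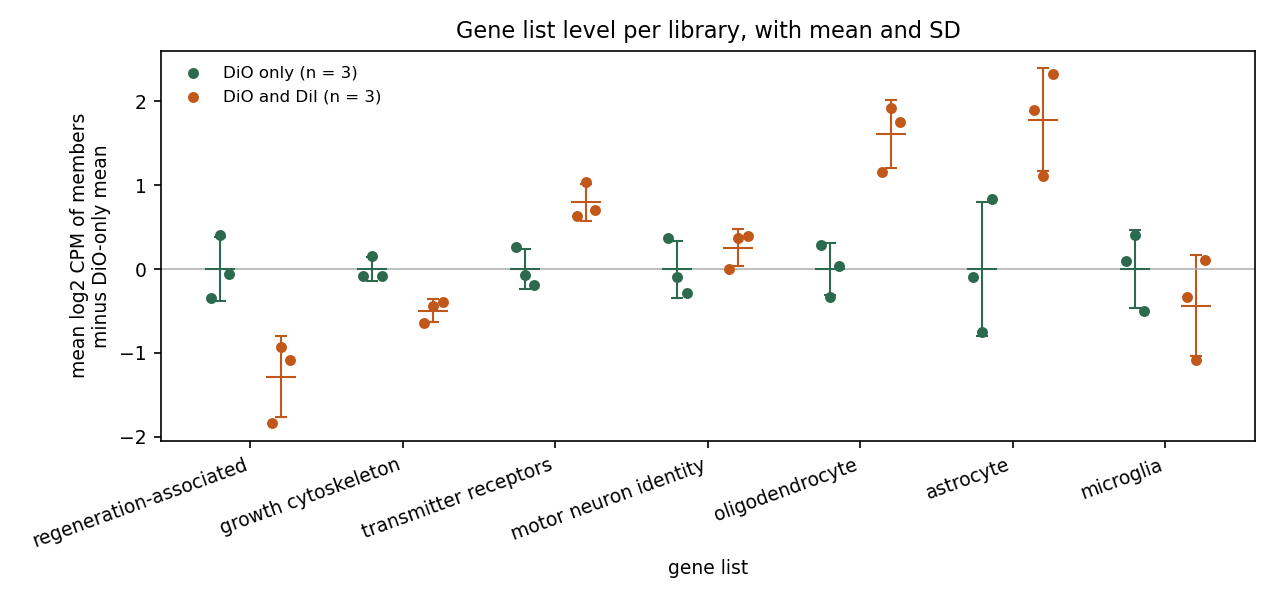
Mean log2 CPM over the tested members of 7 gene lists in each library, relative to the mean of the DiO-only pools, with points for libraries and bars for the mean and SD of 3 libraries. The regeneration-associated list lies lower and the oligodendrocyte and astrocyte lists higher in all 3 double-labelled pools, whereas the motor neuron identity and microglia lists overlap between the groups.

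The genes nearest to the threshold, chosen among those whose groups did not overlap, failed it in edgeR in both directions. The 12 higher genes of smallest p included *Atp1b2*, *Slc1a2*, *Apoe*, *Mobp*, *Tpd52l1*, *Mbp*, *Dkk3*, *Ano3*, *Tmem255a* and *Gpr37l1*, with edgeR adjusted p from 0.308 to 0.357. *Apoe*, of a lipid carrier that glia make, stood at 47.4 ± 5.23 and 437 ± 389 CPM (SD, n = 3). The Wnt modulator gene *Dkk3* stood at 57.6 ± 21.5 and 290 ± 167 CPM, and *Tpd52l1* at 9.73 ± 8.78 and 95.7 ± 46.2 CPM. The 12 lower genes of smallest p were *Ccl8*, *Cyp1b1*, *Tubb6*, *Tm4sf1*, *Serpinb2*, *Pdlim1*, *Rprm*, *Plin2*, *Tuba1c*, *Pde6b*, *Cavin3* and *Lix1*, with edgeR adjusted p from 0.308 to 0.444. Of the genes named so far in this paragraph, DESeq2 called all but *Pdlim1* and *Cavin3*, edgeR without a filter all but *Cavin3*, and edgeR with the replicate block *Apoe*, *Mobp*, *Tpd52l1*, *Mbp*, *Dkk3*, *Tmem255a*, *Ccl8*, *Tubb6*, *Serpinb2*, *Pdlim1*, *Rprm* and *Tuba1c*. *Cyp1b1*, a cytochrome P450 gene, stood at 97.4 ± 29.2 and 27.7 ± 2.99 CPM, *Tm4sf1* at 87.4 ± 29.3 and 16.5 ± 9.76 CPM, and *Plin2*, of a lipid droplet protein, at 98.0 ± 67.1 and 19.7 ± 2.37 CPM. The chemokine gene *Ccl8* had 366 counts in DiO-only pools and 1 in double-labelled pools, a ratio of 345 relative to total counts (95% exact interval 61.4 to 13645). *Serpinb2* and *Pdlim1* had 308 and 517 counts in DiO-only pools and 0 in double-labelled pools, which makes them at least 96.6-fold and 162-fold lower against a floor of 3 counts over the group. *Serpinb2* reached 81.5 CPM in DiO-only pool 2 and *Pdlim1* 81.8 CPM in DiO-only pool 3, and both stayed at or below 7.15 CPM in the remaining DiO-only pools. Such intervals and floors cover counting error only, since amplified reads without molecular identifiers are not independent molecules. *Tmem255a*, *Cavin3* and *Lix1* each overlap another tested gene, so part of their reads is uncertain.

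**Figure D3:**
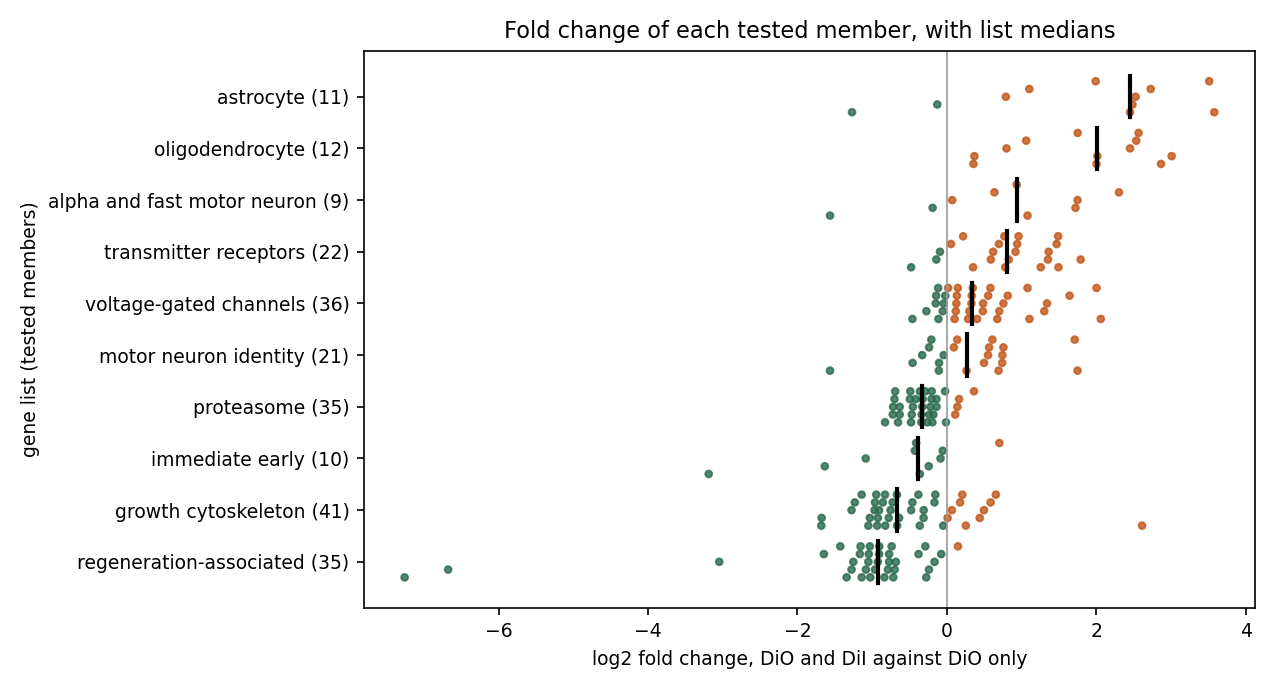
Log2 fold change of every tested member of the 9 gene lists that passed and of the motor neuron identity list, with the number of tested members in brackets. Each point is a gene, green below 0 and orange above, and each black bar is the list median, from -0.93 for the regeneration-associated list to 2.45 for the astrocyte list.

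The remaining lists did not pass. Among lists with more members lower, cholesterol synthesis had 19 of 22 lower (camera adjusted p = 0.0617), glycolysis 13 of 18 (0.0642), cytosolic ribosomal proteins 72 of 80 (0.0736), lysosome and autophagy 22 of 31 (0.173), synaptic vesicle release 20 of 29 (0.343), translation factors 20 of 28 (0.343) and cell death with p53 targets 10 of 17 (0.373). More members were higher for regeneration brakes, 13 of 21 (camera adjusted p = 0.343), matrix and integrins, 40 of 59 (0.343), mitochondrially encoded genes, 10 of 18 (0.343), trophic receptors and ligands, 12 of 19 (0.458), interferon response with MHC class I, 7 of 11 (0.475), and the unfolded protein response, 15 of 26 (0.563). Nuclear oxidative phosphorylation genes and axon guidance genes tested upward with medians of -0.01 and -0.02 (camera adjusted p = 0.563 and 0.803), so that test and median differed in sign. Lists with under 5 tested members were not tested. Their summed CPM in DiO-only and double-labelled pools was 332 ± 472 and 28.3 ± 6.61 for visceral motor neurons (SD, n = 3), 15.9 ± 11.6 and 33.0 ± 14.9 for oligodendrocyte precursors, 1198 ± 74.1 and 1012 ± 159 for Schwann cells, 154 ± 48.0 and 115 ± 172 for fibroblasts, and 2.62 ± 1.27 and 2.60 ± 3.25 for red blood cells. The interneuron list summed to 1713 ± 2715 and 35.5 ± 9.77, but *Npy*, which is on the regeneration-associated list too, made up 92.8% of this over all libraries and 4752 of the 4847 CPM in DiO-only pool 2. Without *Npy* the sum was 103 ± 30.04 and 22.6 ± 10.8. In the visceral, fibroblast and Schwann lists as well a single gene made up most of the sum, 80.9%, 95.3% and 61.1%. For sex-linked genes it was 73.6 ± 34.0 and 100 ± 49.0, and *Xist* had 0 counts in every library.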

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

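Thinning to the smallest library and camera on ranks were chosen after seeing the data, the other alternatives before. The edgeR count of 0 genes stayed at 0 with DESeq2's size factors, total counts only, without mitochondrial and the 20 most counted genes, with the stricter filter, at an adjusted p under 0.1, after thinning, and without each library in turn. limma voom also called 0. Without a filter edgeR called 79 genes (43 higher, 36 lower) and DESeq2 called 75 (39 higher, 36 lower), with 52 genes in common. Besides genes nearest to the edgeR threshold, DESeq2 called *Gal*, *Vip*, *Anxa2*, *Chodl*, *Sparc* and *Ptgds* among the genes named here, and edgeR without a filter *Vip*, *Chodl*, *Mmp9*, *Calca*, *Chrm2*, *Cdkn1a*, *Sparc* and *Ptgds*. At an unadjusted p under 0.05 with a log2 fold change of at least 1 there were 578 genes (349 higher, 229 lower). The cause of these differences was not tested. Spike-in scaling was not run, since the table has no spike-in rows. The median log2 fold change of all genes was 0.02 with TMM, 0.03 with DESeq2's size factors and 0.05 with total counts. No named gene changed direction under any alternative run except *Clu*, *Cst3*, *S100b* and *Aldh1l1*, where *Ndrg1*, *Penk* and *Sst* were not followed through the alternatives. The log2 fold change turned to 0.042 for *Clu* and 0.49 for *S100b* with limma voom, to 0.0081 for *S100b* with total counts, and to -0.0106 for *Cst3* without a filter. Without each library in turn it ran from -0.24 to 0.12 for *Clu*, -0.28 to 0.41 for *Cst3*, -0.47 to 0.79 for *S100b* and -1.85 to 0.46 for *Aldh1l1*.

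The replicate numbers of both groups were used as a block in edgeR, which called 23 genes (12 higher, 11 lower), 18 of them also called by DESeq2, with *Gal*, *Uts2*, *Sprr1a* and *Ptgds* besides genes nearest to the threshold. Deviations from the group means correlated by 0.0742, 0.228 and 0.203 for numbers 1, 2 and 3. The numbers were not taken to pair the samples, since the labels do not say so. Every library correlated best with its own number, a hint from the data, not the design. The libraries numbered 2 had the lowest total counts of their groups. Mitochondrially encoded genes took 10.81% (DiO-only) and 18.02% (double-labelled) of their counts, against 3.96 to 6.13% in the other libraries. Ribosomal RNA genes, mitochondrial ones included, took 1.859% and 1.598%, against 0.539 to 0.691%, a share that overlaps the mitochondrial one. Whether the numbers mark batches or pairs therefore stays open, and the main test would ignore such a pairing. Under the block 9 lists passed, as without it, and the immediate early list was at an adjusted p of 0.0573. With the block the log2 fold change was -0.00607 for *Cst3* and 0.12 for *S100b*, on the other side of 0.

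Of 28 lists, 9 passed with the preset correlation, and 0 with an estimated correlation or with fry. With an estimated correlation the adjusted p was 0.258 for the regeneration-associated and growth cytoskeleton lists, 0.0892 for oligodendrocytes, 0.224 for astrocytes and transmitter receptors, 0.323 for alpha and fast motor neurons, 0.307 for immediate early genes, 0.567 for the proteasome and 0.407 for voltage-gated channels. With fry it was 0.0642 for the regeneration-associated, growth cytoskeleton, oligodendrocyte, astrocyte, transmitter receptor and immediate early lists, 0.176 for alpha and fast motor neurons, and 0.314 for the proteasome and voltage-gated channels. The immediate early list was also lost with the stricter filter (0.291) and on ranks (0.0617). The number of lists was 9 to 12 under the other scaling, the stricter filter, thinning and ranks. Cholesterol synthesis, glycolysis and ribosomal proteins passed downward with the stricter filter (0.0272, 0.0299 and 0.0312), thinning (0.0280, 0.0390 and 0.0451) and ranks (0.0314, 0.0479 and 0.0435), and ribosomal proteins also under the block (0.0103).

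Without each library in turn, 6 (without double-labelled pool 2) to 14 lists (without DiO-only pool 2) passed. The regeneration-associated, growth cytoskeleton, oligodendrocyte, astrocyte and transmitter receptor lists passed each time. The adjusted p ran from 0.00491 to 0.134 for alpha and fast motor neurons, 0.00463 to 0.0977 for immediate early genes, 3.8e-05 to 0.272 for the proteasome and 0.000628 to 0.188 for voltage-gated channels. Among lists that did not pass, it ran from 0.000204 to 0.868 for nuclear oxidative phosphorylation, 0.00322 to 0.721 for mitochondrially encoded genes and 3.3e-05 to 0.608 for ribosomal proteins, each with a turn of direction. It ran from 0.000275 to 0.233 for endothelial and pericyte markers, under 0.05 in 4 of 6 runs, and from 0.0125 to 0.534 for motor neuron identity, 0.0116 to 0.548 for glycolysis and 0.0116 to 0.320 for cholesterol synthesis. Of lists that passed in none of these runs, some turned direction. It ran from 0.361 to 0.868 for trophic receptors, 0.153 to 0.964 for gamma and slow motor neurons, 0.318 to 0.955 for the unfolded protein response, 0.342 to 0.908 for cell death, 0.277 to 0.928 for axon guidance, 0.132 to 0.786 for matrix and integrins and 0.134 to 0.923 for microglia. Gamma and slow motor neurons also turned with the stricter filter (0.669) and thinning (0.834), and axon guidance with fry (0.959). The cause was not tested.

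The mean correlation within groups exceeded that between groups by 0.0139 over all tested genes and by 0.105 over the 1000 most variable genes. Over all tested genes the excess came from the DiO-only pools alone (0.888). The double-labelled pools correlated with each other (0.770) less than with the DiO-only pools (0.815). In simulation of the 12954 filtered genes edgeR recovered 0% of 2-fold changes and DESeq2 3.0%. Most changes of that size would therefore be missed gene by gene among the filtered genes.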

Other observations

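All tests in this part were chosen after the results were seen, except the count of lists over other splits of the libraries.

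Some neuropeptide genes were lower by large folds. Besides *Gal*, *Vip* stood at 42.4 ± 7.39 CPM in DiO-only pools and 5.12 ± 4.45 in double-labelled pools (SD, n = 3), with groups that did not overlap. *Npy* stood at 2006 ± 3414 and 13.6 ± 18.3 CPM, most of it from DiO-only pool 2. *Penk*, scaled by total counts, stood at 847 CPM in DiO-only pool 1 but at 3.47 and 0.962 CPM in pools 2 and 3. *Sst* at 36.9 ± 59.2 and 7.94 ± 6.33 CPM and *Uts2* at 213 ± 263 and 43.5 ± 43.2 CPM also varied widely among DiO-only pools. Part of the large falls therefore rests on single DiO-only libraries. *Calcb* pointed the other way by less, at 341 ± 208 and 572 ± 306 CPM (log2 fold change 0.74 ± 0.47, SE). Of 21 tested neuropeptide genes 12 were lower, 7 with a log2 fold change under -2 and 0 above 2, and none passed in the filtered edgeR fit, while DESeq2 called *Gal* and *Vip*, edgeR without a filter *Vip* and *Calca*, and edgeR with the replicate block *Gal* and *Uts2*. The camera p of all 21 was 0.0160 downward (0.258 with an estimated correlation), which includes the genes that prompted the question. The hypothesis that neuropeptide genes were lower as a group was tested on the 18 members other than *Gal*, *Vip* and *Npy*, of which 9 were lower. Their camera p was 0.236, which leaves the hypothesis undecided.

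Several genes outside the passing lists also had groups that did not overlap, at edgeR adjusted p from 0.357 to 0.617. *Cdkn1a*, a cell cycle inhibitor gene that p53 induces, stood at 306 ± 93.1 and 83.3 ± 76.1 CPM. The guidance receptor genes *Robo2* and *Plxna3* went in opposite directions, *Robo2* at 59.0 ± 19.9 and 17.4 ± 10.2 CPM and *Plxna3* at 15.4 ± 3.06 and 44.0 ± 15.0 CPM. The matrix protein gene *Sparc* stood at 35.0 ± 19.5 and 181 ± 109 CPM.

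The regeneration-associated list was lower in double-labelled pools, the cells marked by their early regrowth. Dilution of neuronal RNA by glial RNA would lower motor neuron genes as well, but the score of the motor neuron identity list differed by 0.26 ± 0.23 (SE, log2) while that of the regeneration-associated list differed by -1.28 ± 0.36. The score weights all members alike. Summed CPM of the identity list was 44144 ± 12618 in DiO-only and 39619 ± 7569 in double-labelled pools (SD, n = 3), against 37410 ± 8976 and 15690 ± 4384 for the regeneration-associated list. Whether the identity genes themselves respond to injury was not tested, which limits their use as a control. Lower complexity of the libraries would spare abundant genes. The 24 members with a mean of at least 100 CPM had a median log2 fold change of -0.93, however. That lay below all of 10000 random sets matched on expression, whose lowest median was -0.61. The random genes were drawn singly and lack the correlation between list members, estimated at 0.229. This comparison therefore cannot exclude lower complexity. A share of neurons without an injury response among the double-labelled cells cannot be told apart from a lower response in every cell, since no uninjured neurons were sampled here, and the median fold would need 47.3% of such neurons if they lacked these transcripts. That share stands for the median only, since members fell by unlike factors. The double-labelled mean was 0.00990 of the DiO-only mean for *Gal* and 0.454 for *Gap43*. Other explanations were not tested, among them the share of interneurons, although cells were picked by their dye. The summed CPM of interneuron markers without *Npy* was also lower in double-labelled pools, but that list was not tested. Its member *Slc17a6* had overlapping groups, at 26.2 ± 31.5 and 6.84 ± 5.13 CPM (SD, n = 3).

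Oligodendrocyte and astrocyte markers were higher in double-labelled pools. A lower share of motor neuron RNA would raise the markers of every other cell type alike, but the score of microglia markers differed by -0.44 ± 0.44 (SE, log2) against 1.61 ± 0.29 for oligodendrocytes. Only 7 of 18 microglia markers had enough counts for the test. The whole microglia list summed to 106 ± 15.3 CPM in DiO-only and 101 ± 58.3 CPM in double-labelled pools (SD, n = 3). Low counts therefore limit this comparison. RNA or cells of oligodendrocytes and astrocytes collected with the neurons remain a candidate explanation, although cells were picked by their dye. Of 30 other transcripts abundant in these glia, 23 were higher, with a median log2 fold change of 0.82 (camera p = 6.9e-06, and p = 0.0112 with an estimated correlation), led by *Ptgds* at 16.3 ± 11.1 and 118 ± 67.7 CPM, while *Clu* at 1151 ± 309 and 1113 ± 191 CPM and *Cst3* at 703 ± 321 and 707 ± 310 CPM did not separate. *Ndrg1* went the other way, at 41.7 ± 23.3 and 13.0 ± 7.08 CPM (log2 fold change -1.69 ± 0.59, SE). Of the 23 markers on both lists 13 had a mean of at least 5 CPM in DiO-only pools and 2 stand on another list, and a difference in glia close to the double-labelled neurons was not tested.

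The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 5%. The real split gave 0 genes with an adjusted p under 0.05 in edgeR, as did all 10 splits, the highest of the others being 0. At an unadjusted p under 0.05 the real split gave 753 genes and the highest of the others 1273. The real split gave 9 lists past the threshold and the highest of the others 7, so that 1 of the 10 splits gave as many. Single lists reached a smaller camera adjusted p in other splits, down to 1.1e-26, than the 5.4e-12 of the regeneration-associated list in the real split. That list itself also passed in other splits (camera adjusted p = 0.00507, 0.00202, 7.5e-06 and 2.2e-05). So did the oligodendrocyte (0.0314 and 0.00986), transmitter receptor (0.0114 and 0.00579) and astrocyte lists (0.000639 and 0.0355). Each of these values was larger than that of the same list in the real split. Without the 5 genes it shares with that list, the growth cytoskeleton list was still lower, since its other 36 members had a median log2 fold change of -0.47 with 26 lower (camera p = 0.00172, and p = 0.0815 with an estimated correlation).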
